A study of Mus musculus with 18 samples.

How the data were processed

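RNA from the interscapular brown fat of C57BL/6 mice was sequenced (Trizol extraction, TruSeq libraries) in 18 samples. The mothers ate a control diet or a fish oil diet through pregnancy and lactation, and the offspring were sampled as fetuses, at weaning (3 weeks) or as adults (15 weeks, after 8 weeks on a high fat diet). This gave 6 groups of 3 libraries. The labels number the replicates 1 to 3 but do not say whether they came from different litters or whether fetal samples were pools of several fetuses. Xist was at 138.9 to 329.3 CPM in 4 of the 6 fetal libraries, all of which expressed the Y-linked gene Ddx3y. The small fetal spread is therefore not taken as the spread between single animals, and the p-values measure the spread between these samples only. For adult fish oil library 2 the source name gives replicate 3, and the number in its title was used; the replicate block and the pairing of numbers depend on that choice. The numbers were not taken to pair the samples. Of 9 pairs of fish oil and control libraries of the same age and number, 2 had a correlation above 0.1, with a range of -0.49 to 0.29. With 3 libraries per group these values cannot show that pairing is absent.

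Each deposited file holds raw counts per Ensembl gene for 55416 genes, in 3 columns (unstranded, forward and reverse). Per the submitters' processing notes the reads were processed with Bowtie 0.12.2 and STAR, and the notes name the mm8 and mm9 builds. The annotation behind the counts is not given in the sources used here, so no coordinates are printed. The total of the forward column came to 98.9 to 99.5% of that of the unstranded column in each library. The forward column was used throughout; that choice was made from the column totals, before any test. Gene symbols were matched by Ensembl identifier for 52083 genes, which hold 99.97% of the counts, and identifiers with no symbol were left as they are.

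Forward totals ran from 7889595 to 17943071 counts per library. The mitochondrial rRNA gene mt-Rnr2 took 43.35 to 61% of them and mt-Rnr1 3.7 to 8.03%, which left 3869067 to 7460408 counts for the other genes. A floor of 3 counts in a library corresponds to 0.145 to 0.433 CPM. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

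Counts were filtered with filterByExpr, scaled with trimmed mean of M values (TMM) factors and fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3. All 18 libraries were fitted together in 6 groups that share a single estimate of the spread, and 14366 genes (25.9%) were tested. The comparisons were fish oil against control at each of the 3 ages, the 3 differences between these diet effects, and weaned against fetal and adult against weaned averaged over both diets. P-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05 and no fold limit. Errors after a log2 fold change are standard errors of the fit, and errors after a mean are SDs over 3 libraries. The libraries of each age were also fitted alone, and those calls are given beside the shared fit because the spread differed between ages. The biological coefficient of variation was 8.98% in fetal, 26.8% in weaned and 19.6% in adult libraries, and 20.6% in the shared fit.

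Gene lists of brown fat function, lipid metabolism, mitochondria, stress, clock and other cell types were written before the data were examined, as were the groups, tests, thresholds, named-gene rule and most alternative settings. Lists written for lymphocytes, epidermis and cartilage or bone had 3 tested members each and were only counted. The 29 lists hold 725 symbols, of which 589 were tested; 26 lists had at least 5 tested members. They were compared with all other tested genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Each call was repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Diet effects at 2 ages were compared by correlation across genes, with p-values from 100 relabellings of diet within each age.

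Named genes followed a fixed rule: 8 genes always given (Ucp1, Ppargc1a, Prdm16, Cidea, Dio2, Elovl3, Ffar4 and Fgf21), then for each diet comparison the 12 highest and 12 lowest log2 fold changes among genes that passed, did not overlap between groups and had a mean of at least 5 CPM in the higher group. Predicted genes, clones and pseudogenes were left out of the naming. The rule also gave the first members of each list that passed, the 8 highest and 8 lowest genes of the age comparisons and the 10 lowest adjusted p-values of the differences between diet effects. Applying the same order to the separate fits was a choice made after the data were seen. Some genes that the rule gives are not reported here. Any gene outside the rule is said to have been chosen after its values were seen. The exceptions are Xist and Ddx3y, from a list of sex-linked genes that was written beforehand and left out of the list test.

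The fits were tested on simulated data with the group sizes, depths and spreads of these libraries. Genes were drawn independently of each other, with changes planted in a single diet comparison. The shares of false calls are therefore not rates for the real calls, where genes vary together. For fetal libraries the shared fit recovered 0% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 95.5% of those changed 4-fold, with 1.1% false calls. The fetal fit alone recovered 49.3, 83.6 and 100% with 10.9% false calls. For weaned libraries the shared fit recovered 19.4, 62.7 and 95.4%, but 44.8% of its calls (95 of 212) were false, and the weaned fit alone recovered 0, 12.3 and 75% with 9.7% false. For adult libraries the shared fit recovered 14.9, 50.7 and 90.9% with 14.8% false calls, and the adult fit alone 12.1, 44.4 and 90.3% with 8% false.

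The alternatives were DESeq2 1.42.0, relative log expression factors, no filter, a filter of at least 50 counts in 3 libraries, limma-voom with sample quality weights, a replicate block, a 1.5-fold limit, removal of mitochondrial, erythroid and muscle list genes, separate fits and leaving out each library. Unstranded counts, removal of the mitochondrial rRNA genes, scaling by library size alone, and covariates for muscle genes or Xist were added after the data were seen. Directions of lists were checked under each scaling. The reverse column was not used in any comparison.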

Results

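The series measured gene expression by RNA sequencing in mouse interscapular brown fat, a thermogenic fat depot, from offspring of mothers fed a control or a fish oil diet. There were 3 libraries in each of 6 groups: fetal, weaned and adult offspring of either maternal diet. The forward counts per library were 9434710 to 13971209 in fetal control and 10146103 to 16263663 in fetal fish oil libraries. They were 14855294 to 17943071 in weaned control and 14755725 to 15938609 in weaned fish oil libraries. Adult control libraries held 9232037 to 9663600 and adult fish oil libraries 7889595 to 9420612 counts. The mitochondrial rRNA gene mt-Rnr2 took 58.36 to 61% of the counts in weaned control and 53.12 to 54.92% in weaned fish oil libraries, and 43.35 to 51.81% in the other groups. The first principal component of the log2 CPM values carried 47.7% of the variance and the second 14.5%.

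The fetal comparison asked which genes differed before birth with the diet of the mother. Snx10, which encodes an endosomal sorting nexin, fell from 15.0 ± 2.68 CPM in control to 5.20 ± 0.327 CPM in fish oil libraries (mean ± SD, n = 3 each; log2 fold change -1.53 ± 0.179, edgeR adjusted p = 0.00154). Setd7, a lysine methyltransferase, fell from 45.8 ± 1.23 to 24.7 ± 2.84 CPM (log2 fold change -0.89 ± 0.12, adjusted p = 0.00372). Rasd1, a small GTPase induced by glucocorticoids, fell by 1.80 ± 0.281 on the log2 scale (adjusted p = 0.0121), and Prodh, which starts the breakdown of proline, fell by 1.55 ± 0.263 (adjusted p = 0.0248). Aspg, Grk3, Cnnm2 and the transcription factor gene Zbtb20 fell by 1.66, 1.08, 0.81 and 0.57, with adjusted p-values of 0.00794, 0.0295, 0.00485 and 0.0176. Zfp395 and Shprh, which encodes a ubiquitin ligase, rose by 0.94 ± 0.163 and 0.61 ± 0.108 (adjusted p = 0.0295 and 0.0297). Of 14366 genes tested, 14 passed, 3 higher and 11 lower with fish oil, and 923 had an unadjusted p under 0.05. The fish oil and control libraries did not overlap for these 14 genes, nor for 21.9% of all genes tested, where chance gives 10%. Leaving out a library left 9, 7 or 10 genes without control replicates 1, 2 or 3 and 6, 2 or 8 genes without fish oil replicates 1, 2 or 3.

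In a fit of the fetal libraries alone, 604 of 13331 genes passed, 253 higher and 351 lower, and 13 of the 14 genes above were among them. Scd1, the main desaturase of fatty acid synthesis, fell from 1107 ± 97 to 465 ± 74.9 CPM (log2 fold change -1.25 ± 0.0976, adjusted p = 1.02e-05). The elongase gene Elovl6 fell by 0.93 ± 0.0777 (adjusted p = 1.49e-05) and Agpat2, an acyltransferase of triglyceride synthesis, by 1.06 ± 0.161 (adjusted p = 0.00171). Hmox1, which degrades haem, fell from 59.7 ± 8.92 to 17.6 ± 3.51 CPM (log2 fold change -1.79 ± 0.131, adjusted p = 1.02e-05), and the metallothionein gene Mt2 fell by 1.68 ± 0.168 (adjusted p = 7.54e-05). Pck1, the key enzyme of glyceroneogenesis, rose from 854 ± 107 to 1955 ± 234 CPM (log2 fold change 1.19 ± 0.0921, adjusted p = 1.02e-05). The sarcomere genes Myh2, Myoz2 and Myh3 rose by 1.60, 1.40 and 1.32 (adjusted p = 0.00237, 0.00716 and 0.0124). Ucp1, the uncoupling protein of brown fat, fell from 2083 ± 342 to 1191 ± 221 CPM (adjusted p = 0.00165) and Dio2, which activates thyroid hormone, from 201 ± 26.3 to 90.7 ± 29.3 CPM (adjusted p = 0.00104). In the shared fit the adjusted p-values of these 11 genes were between 0.282 for Elovl6 and 0.857 for Dio2. The count in fetal libraries alone was 298 without control replicate 1, 315 without control replicate 2 and 389 without fish oil replicate 2.

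Among the gene lists in the fetal libraries, skeletal muscle genes, which encode sarcomere and calcium handling proteins, were higher as a list with fish oil (median log2 0.93, 35 of 35 positive, camera adjusted p = 8.86e-07, and p = 0.743 with an estimated correlation). The muscle list mean was 4.05 ± 0.356 log2 CPM in fish oil and 3.14 ± 0.429 in control libraries. None of the 35 genes passed over all genes or adjusted over the list alone in edgeR, and 20 rose in the separate fit. Mitochondrially encoded genes were lower (median -0.30, 8 of 8 negative, adjusted p = 4.58e-06, 0.254 with an estimated correlation). Of these genes, 4 were lower adjusted over the list alone, and mt-Nd2 gave -0.49. Oxidative stress response genes were lower (median -0.23, 20 of 25 negative, adjusted p = 8.35e-05, 0.0662 with an estimated correlation). Of these, 1 was lower adjusted over the list alone and 9 in the separate fit, among them Hmox1, Mt2, Srxn1 and G6pdx. Fatty acid synthesis genes were lower (median -0.19, 18 of 22 negative, adjusted p = 0.000289, 0.743 with an estimated correlation). Of these, 4 were lower adjusted over the list alone and 9 in the separate fit. Genes of the tricarboxylic acid cycle were lower (median -0.11, adjusted p = 0.0239, 0.956 with an estimated correlation). The other 21 lists did not pass, thermogenic genes included (median -0.10, adjusted p = 0.159).

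Of the other fixed genes in the fetal libraries, Ppargc1a (log2 fold change -0.03 ± 0.252), Prdm16 (0.05 ± 0.225), Cidea (0.12 ± 0.187) and the fish oil receptor gene Ffar4 (-0.26 ± 0.374) did not pass in either fit. Elovl3 (-1.93 ± 1.07) had an adjusted p of 0.844 in the shared and 0.0465 in the separate fit, at 0.594 CPM with fish oil and 2.47 CPM in control. Fgf21 had 24 counts over the 18 libraries and 0 in 9 of them, and was not tested.

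**Figure D1:**
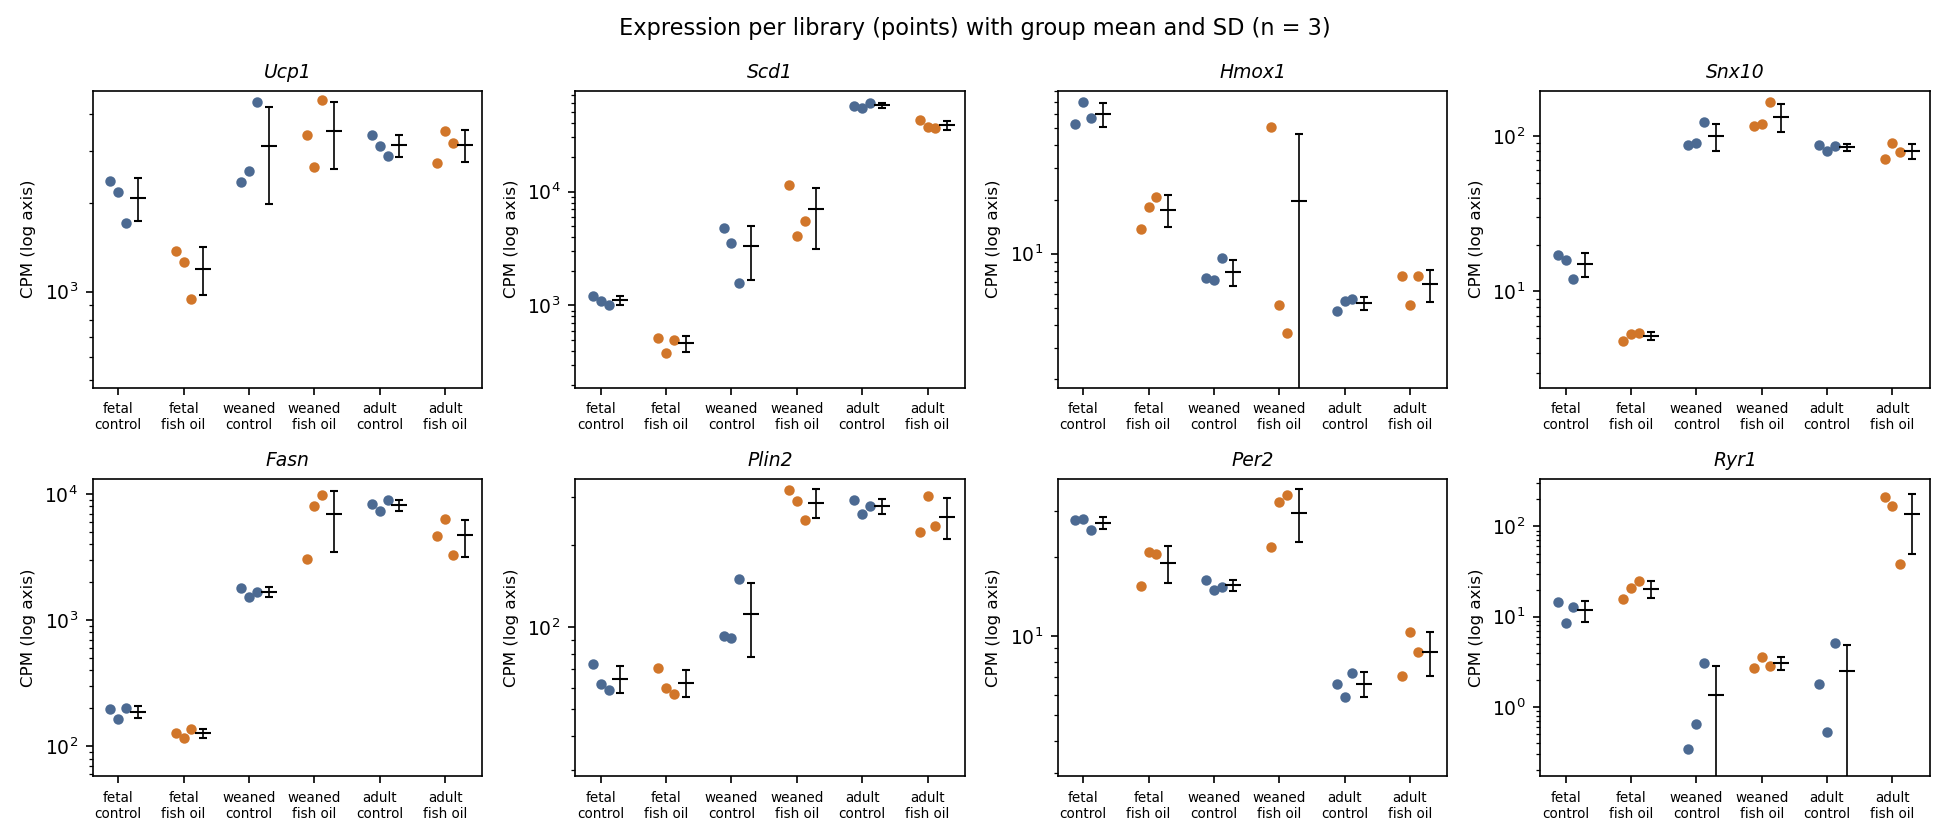
CPM (log axis) of Ucp1, Scd1, Hmox1, Snx10, Fasn, Plin2, Per2 and Ryr1 in each of the 18 libraries by group, with the group mean and SD (n = 3; a bar whose SD exceeds its mean runs to the bottom of the axis). Plin2 was 286 ± 35 CPM in weaned fish oil against 111 ± 33.6 CPM in weaned control, and Ryr1 138 ± 89.4 CPM in adult fish oil against 2.48 ± 2.38 CPM in adult control libraries.

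The weaned comparison asked which genes differed at the end of lactation on the maternal diet. Fasn, the fatty acid synthase, rose from 1671 ± 147 CPM in control to 6980 ± 3530 CPM in fish oil libraries (n = 3 each; log2 fold change 2.06 ± 0.303, edgeR adjusted p = 0.0111), and Slc25a1, the mitochondrial citrate carrier, from 17.2 ± 3.08 to 115 ± 81.2 CPM (2.74 ± 0.479, adjusted p = 0.0252). Plin2, which coats lipid droplets, rose from 111 ± 33.6 to 286 ± 35 CPM (1.36 ± 0.178, adjusted p = 0.00496). The clock gene Per2 rose by 0.92 (adjusted p = 0.0309). Cyp51 and Insig1, of the cholesterol pathway, rose by 1.30 and 1.11 (adjusted p = 0.0252 and 0.0327). Trarg1, Nabp1, Aacs, Nat8l, Hspa8, Dvl2 and Klf10 rose by 1.12 to 1.51. Rgs2, a regulator of G protein signalling, fell by 2.25 ± 0.39 (adjusted p = 0.0252), Depp1 by 2.21 and the nucleoside transporter gene Slc29a1 by 1.24 (adjusted p = 0.0353 and 0.0111). Prkag2, Cep126, Trim3 and Hipk3 fell by 0.79, 0.78, 0.64 and 0.62. In all, 38 genes passed, 31 higher and 7 lower, and 1915 had an unadjusted p under 0.05. The 2 groups did not overlap for 37 of the 38 and for 10.2% of all genes tested, where chance gives 10%. With the weaned libraries fitted alone, edgeR called 0 of 12699 genes (643 with an unadjusted p under 0.05), DESeq2 18 and limma-voom 0 (2719 with an unadjusted p under 0.05), and edgeR called 50 without fish oil replicate 1. In the shared fit the count was 5, 4 or 371 without control replicates 1, 2 or 3 and 1632, 2 or 8 without fish oil replicates 1, 2 or 3.

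In the weaned libraries 8 lists were higher and 3 lower with fish oil. Fatty acid synthesis genes had a median log2 fold change of 1.26 (20 of 22 positive, 2 called over all genes, 17 adjusted over the list alone, camera adjusted p = 7.03e-11). Their list mean was 6.04, 6.25 and 6.75 log2 CPM in the control libraries and 6.20, 7.93 and 8.00 in the fish oil libraries, so that fish oil replicate 1 lay within the control range. Cholesterol synthesis genes had a median of 0.61 (23 of 24 positive, 12 adjusted over the list alone, adjusted p = 9.98e-11). Nuclear genes of oxidative phosphorylation gave 0.27 (60 of 60 positive, 7 adjusted over the list alone, adjusted p = 1.09e-15). Fatty acid oxidation genes gave 0.26 (24 of 24 positive, 7 adjusted over the list alone, Cpt2 called at 0.51, adjusted p = 9.83e-08), and tricarboxylic acid cycle genes gave 0.23 (18 of 18 positive, 3 adjusted over the list alone, adjusted p = 2.38e-07). Lipolysis genes gave 0.16 with Plin2 and Mgll called (adjusted p = 0.00345). For these 6 lists the adjusted p was 0.2 with an estimated correlation. Fish oil replicate 1 also lay within the control range of the list mean for cholesterol synthesis (2.35 against 2.21 to 2.55), oxidative phosphorylation (6.14 against 6.06 to 6.23) and tricarboxylic acid cycle genes (8.48 against 8.37 to 8.57), so that replicates 2 and 3 carried these rises. For lipolysis genes replicate 3 lay within that range (6.66 against 6.38 to 6.71). The fatty acid oxidation list mean lay above the control range in each fish oil library, at 6.83 to 6.99 against at most 6.79 in control. Circadian clock genes had a median of 0.40 (14 of 19 positive, 6 adjusted over the list alone, adjusted p = 0.000239, 0.0265 with an estimated correlation). Their list mean was 3.66 to 3.71 in control and 4.06 to 4.16 in fish oil libraries. Endothelial, white adipocyte and fibroblast genes were lower, with medians of -0.18, -0.61 and -0.26 (adjusted p = 0.000152, 0.000642 and 0.00168; 0.2, 0.2 and 0.707 with an estimated correlation), and their list means overlapped between the groups.

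Skeletal muscle genes gave a median of 1.42 in the weaned libraries (33 of 35 positive, 0 adjusted over the list alone, adjusted p = 4.41e-09, 0.367 with an estimated correlation). Their list mean was -0.783, -0.606 and 1.26 log2 CPM in control replicates 1 to 3 and 1.26, 1.49 and 1.32 in the fish oil libraries. Ucp1 was at 3509 ± 909 CPM with fish oil and 3116 ± 1130 CPM in control (log2 fold change 0.17 ± 0.225, adjusted p = 0.779). Ppargc1a (-0.10 ± 0.253), Prdm16 (0.62 ± 0.221), Cidea (0.36 ± 0.187), Dio2 (-0.56 ± 0.649), Elovl3 (1.82 ± 0.702) and Ffar4 (-0.18 ± 0.332) did not pass. Among PPAR target genes, 2 of 24 were called, Plin2 among them, and the list did not pass (adjusted p = 0.871).

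**Figure D2:**
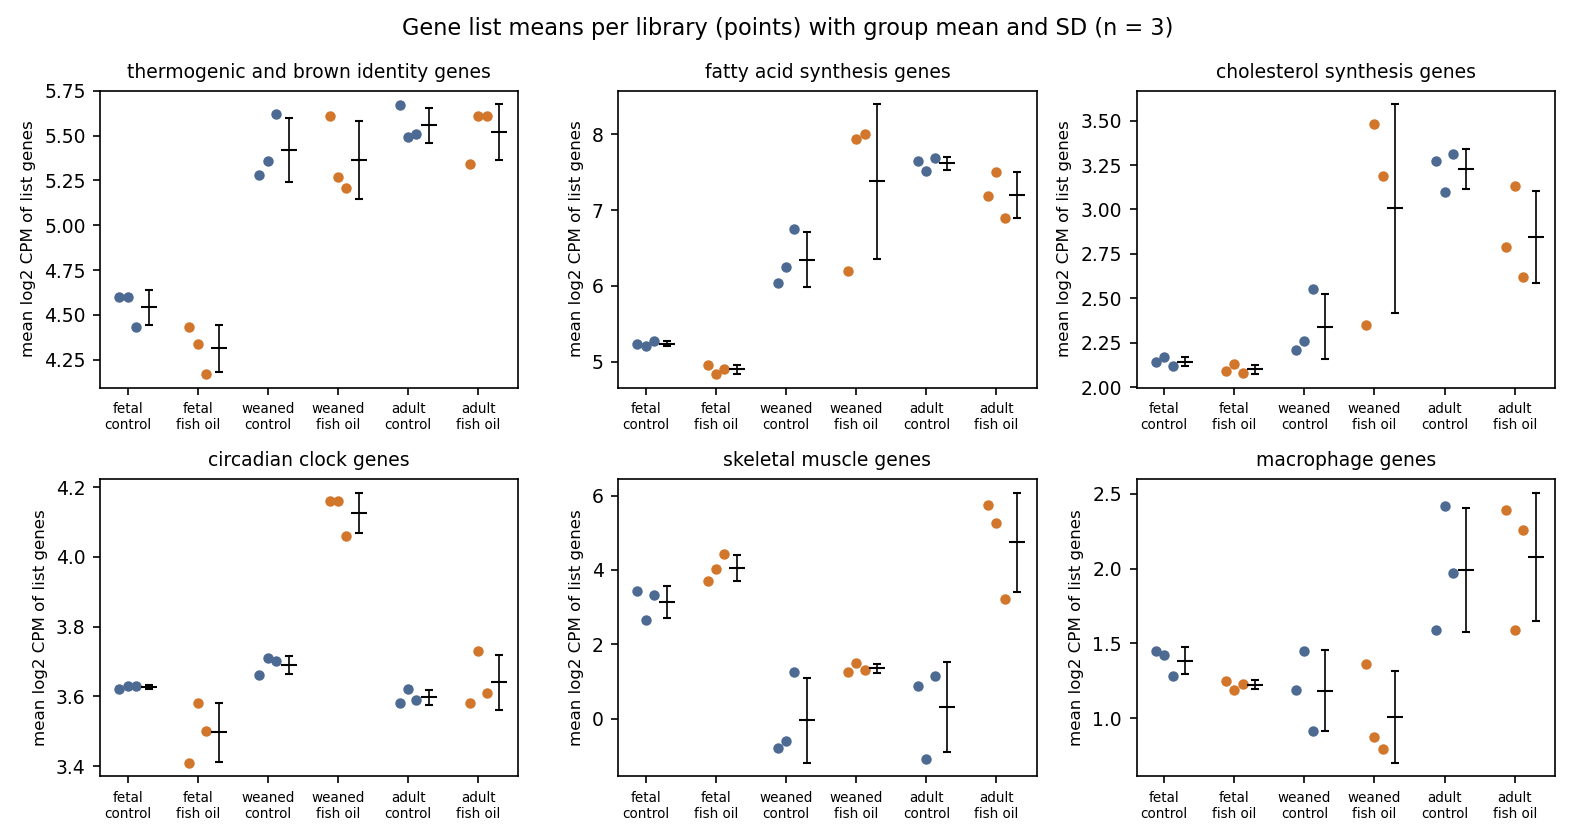
Mean log2 CPM of the genes of 6 lists in each library by group, with the group mean and SD (n = 3). The circadian clock list lay at 4.06 to 4.16 in weaned fish oil and 3.66 to 3.71 in weaned control libraries, and the skeletal muscle list at 3.23 to 5.74 in adult fish oil and -1.07 to 1.14 in adult control libraries.

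The adult comparison asked which genes differed after a high fat diet in offspring of the same maternal diets. Of the skeletal muscle genes, 29 of 35 rose with fish oil over all genes and 33 adjusted over the list alone, with a median log2 fold change of 5.27 (camera adjusted p = 5.04e-60, 0.0396 with an estimated correlation). The median was 5.26 with Tnnt1, at 0 counts in control, set to 3 counts over that group. Ryr1, the calcium release channel of muscle, rose from 2.48 ± 2.38 CPM in control to 138 ± 89.4 CPM in fish oil libraries (n = 3 each; log2 fold change 5.83 ± 0.693, edgeR adjusted p = 0.000406). Myot and Klhl31 rose by 5.77 ± 0.741 and 5.75 ± 0.852 (adjusted p = 0.000431 and 0.00109), and Ckmt2, a creatine kinase, and Pvalb, a calcium buffer of fast muscle, by 6.44 ± 0.718 and 6.21 ± 0.791 (adjusted p = 0.000394 and 0.000431). Myh7 rose by 7.40 ± 1.25 (adjusted p = 0.00342), with 6 counts over the 3 control libraries. Lmod2, Mylk2, Ano5, Mypn and Scn4a also passed, but had 2, 3, 2, 3 and 4 counts over the control libraries, so no fold is given. The list mean was 5.74, 5.27 and 3.23 log2 CPM in the fish oil and 0.872, -1.07 and 1.14 in the control libraries. Trmt9b, a tRNA methyltransferase gene, fell by 0.85 ± 0.173 (adjusted p = 0.0177). Of the genes tested 142 passed, 139 higher and 3 lower, and 980 had an unadjusted p under 0.05. Of the 139 higher genes, 110 lay outside the muscle list. Of these 110, 95 had a correlation above 0.9 with the muscle list mean over the 6 adult libraries. The groups did not overlap for 141 of the 142 and for 14.1% of all genes tested, where chance gives 10%. The count was 89 without control replicate 2.

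With the adult libraries fitted alone, 89 of 11800 genes passed, 83 higher and 6 lower, and 79 of them were among the 142. Scd1 fell from 57130 ± 2730 to 38500 ± 3390 CPM (adjusted p = 0.0341, against 0.84 in the shared fit). That fit called 0 genes in edgeR without control replicates 1, 2 or 3 or fish oil replicate 1 (845, 827, 987 and 918 genes with an unadjusted p under 0.05; DESeq2 121, 126, 143 and 106; limma-voom 0), and 190 without fish oil replicate 3. Fatty acid synthesis genes were lower as a list in the shared fit (median -0.49, 18 of 22 negative, 0 adjusted over the list alone, camera adjusted p = 0.00174, 0.979 with an estimated correlation). Cholesterol synthesis genes were lower too (median -0.36, 21 of 24 negative, 1 lower adjusted over the list alone, adjusted p = 6.04e-05, 0.823 with an estimated correlation). Erythroid genes were lower (median -0.61, 10 of 12 negative, adjusted p = 0.00956, 0.913 with an estimated correlation), although Sptb, a spectrin also present in muscle, rose by 4.25 (adjusted p = 0.00163). Fibroblast and matrix genes were higher (median 0.21, adjusted p = 0.009, 0.996 with an estimated correlation). The list means of cholesterol synthesis, erythroid and fibroblast genes overlapped between the groups. Ube2c was the called member of the proliferation list (3.55, adjusted p = 0.0123). Without fish oil replicate 3, 2 lists passed in place of 5. Ucp1 was at 3149 ± 394 CPM with fish oil and 3137 ± 266 CPM in control (0.01 ± 0.225). Ppargc1a (0.59 ± 0.255), Prdm16 (-0.19 ± 0.221), Cidea (-0.14 ± 0.187), Dio2 (0.74 ± 0.664), Elovl3 (-0.95 ± 0.71) and Ffar4 (0.46 ± 0.338) did not pass.

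**Figure D3:**
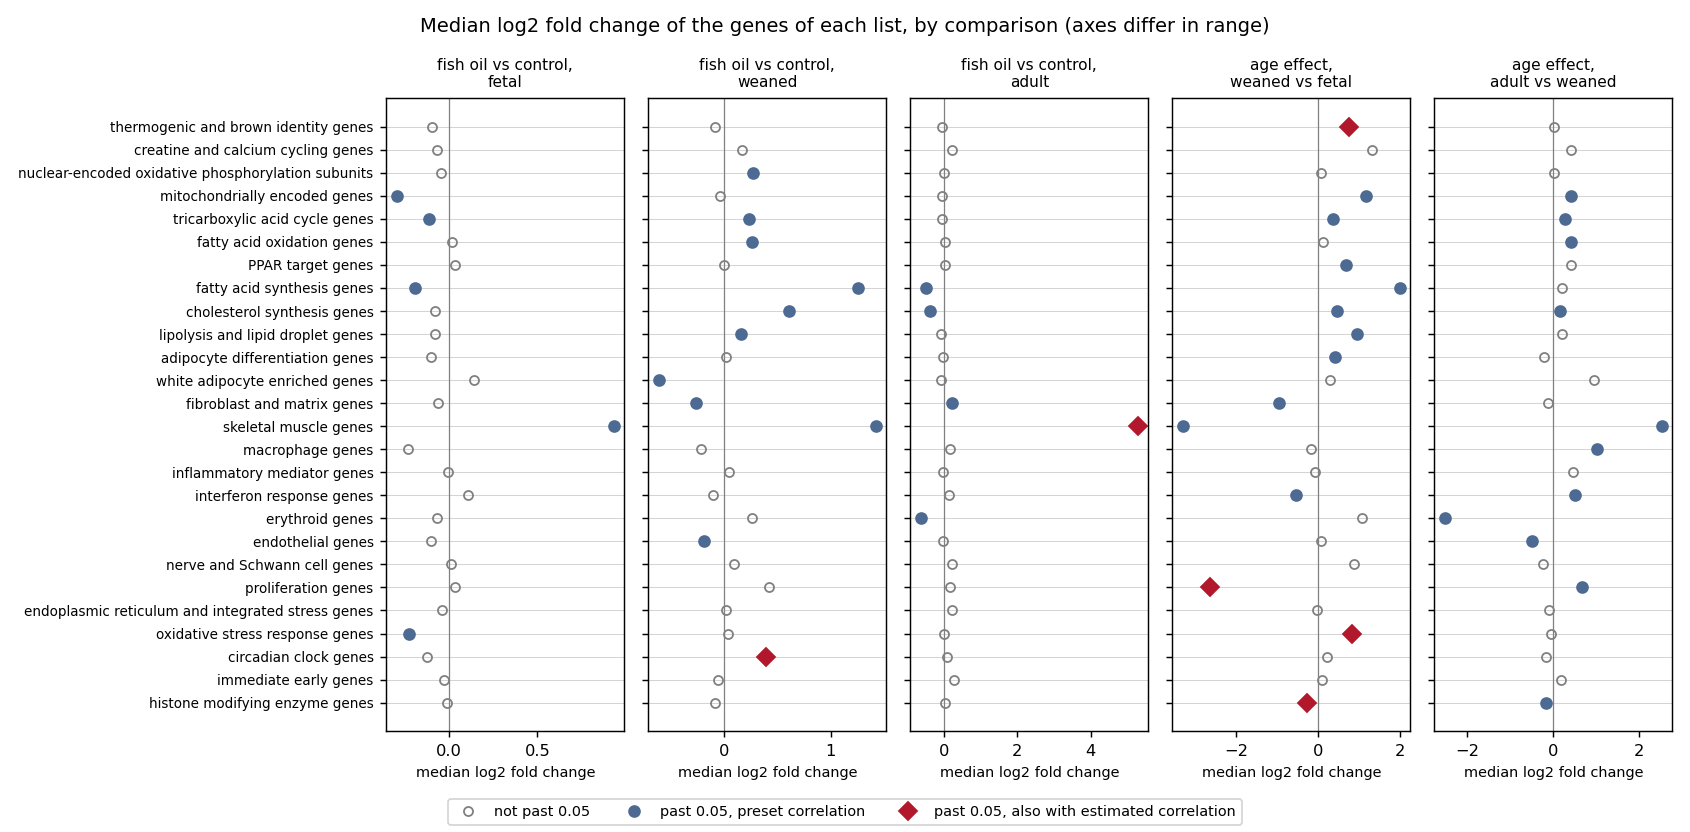
Median log2 fold change (horizontal axis) of each of the 26 tested gene lists in the 3 diet and 2 age comparisons; open grey points did not pass at an adjusted p of 0.05, blue points passed with the preset correlation and red diamonds also with an estimated correlation. The largest diet median was 5.27, for skeletal muscle genes in adult libraries, and the proliferation list had a median of -2.64 from fetal to weaned libraries; scaling by library size alone turned some age medians, as the text on age gives.

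The differences between diet effects at 2 ages were tested directly. The diet effect on Fasn was lower in adult than in weaned libraries (log2 difference -2.85 ± 0.42, edgeR adjusted p = 0.0182), and Plin2 and Insig1 differed by -1.49 and -1.85 (adjusted p = 0.0196 for both). Snx10 and Setd7 had higher diet effects in weaned than in fetal libraries, by 1.94 ± 0.238 and 1.24 ± 0.168 (adjusted p = 0.00429 and 0.00519). The muscle genes Ryr1 and Ckmt2 had higher diet effects in adult than in fetal libraries, by 5.04 ± 0.87 and 5.46 ± 0.915 (adjusted p = 0.0221 and 0.0208). In all, 18 genes differed between weaned and fetal (14 higher and 4 lower; 1408 with an unadjusted p under 0.05), 24 between adult and fetal (22 and 2; 1010) and 36 between adult and weaned libraries (21 and 15; 1529). The larger direction of the last turned when libraries were scaled by size alone (42.9% higher) and with limma-voom (37.8%). Fits of only the ages compared called 5, 186 and 1 genes, of which 5, 24 and 1 were shared with the counts above. The 186 genes between adult and fetal libraries were 108 higher and 78 lower, a more even balance than in the shared fit. Between weaned and fetal libraries the count was 7, 6, 4 and 10 without fetal control replicates 1 or 2 or fetal fish oil replicates 2 or 3. It was 5, 8 and 147 without weaned control replicates 1 to 3 and 467 without weaned fish oil replicate 1. Between adult and fetal libraries it was 3, 3 and 10 without adult control replicates 1 to 3, and 3, 7 and 104 without adult fish oil replicates 1 to 3. It was 3 and 7 without fetal control replicates 1 or 3 and 4, 2 and 4 without fetal fish oil replicates 1 to 3. Between adult and weaned libraries it was 1, 2 and 15 without adult control replicates 1 to 3, and 1, 21 and 80 without adult fish oil replicates 1 to 3. It was 6, 10 and 116 without weaned control replicates 1 to 3, and 813, 1 and 1 without weaned fish oil replicates 1 to 3.

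The comparison of weaned with fetal libraries asked which genes changed with age over both diets. Xist was at 138.9 to 329.3 CPM in most fetal libraries and at most 2.127 CPM in weaned libraries. The mix of sexes thus differed along with age, and their effects cannot be separated here. Acot11, a thioesterase induced by cold, rose by 5.17 ± 0.399 on the log2 scale (averages of both diets; edgeR adjusted p = 2.17e-08). Slc25a48 and Cyp2b10 rose by 5.86 and 5.73 (adjusted p = 8.29e-07 and 1.53e-10), and Kng2 and the glycogen synthase gene Gys2 by 5.70 and 5.58 (adjusted p = 5.61e-12 and 1.48e-09). Fabp3, a fatty acid carrier, rose by 4.89 ± 0.277 (adjusted p = 5.52e-10). Pnpla3 and Fasn rose by 4.51 and 4.47 (adjusted p = 2.04e-06 and 2.68e-10) and Adrb3, the adrenergic receptor of brown fat, by 3.89 (adjusted p = 4.01e-08). Fetal myosin genes fell, Myh8 by 6.48 ± 0.443 and Myh3 by 5.99 ± 0.423 (adjusted p = 5.29e-09 and 8.01e-09), as did the imprinted growth genes H19, Dlk1 and Igf2 by 5.01, 4.97 and 4.56 (adjusted p = 1.23e-08, 6.09e-13 and 5.83e-10). The neutrophil genes S100a8 and S100a9 fell by 5.22 and 5.16 (adjusted p = 3.27e-07 and 6.55e-11) and the mitosis genes Bub1 and Birc5 by 4.02 and 3.84 (adjusted p = 2e-05 and 7.32e-07). Of 14366 genes 7478 passed, 3885 higher and 3593 lower (8259 with an unadjusted p under 0.05). Scaling by library size alone, added after the data were seen, shifted the median of all genes by -0.58 and gave 1289 higher and 8813 lower, so these directions are relative to the typical gene under TMM.

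Of the 26 lists, 9 rose and 5 fell from fetal to weaned libraries. Proliferation genes fell (30 of 32 over all genes, 30 adjusted over the list alone, median -2.64, camera adjusted p = 2.29e-14). So did histone modifying enzyme genes (17 lower and 5 higher, median -0.26, adjusted p = 0.00121). Thermogenic genes rose (16 higher and 3 lower of 25, median 0.77, adjusted p = 0.000623) along with oxidative stress response genes (17 higher and 3 lower, median 0.83, adjusted p = 0.000465). These 4 lists had an adjusted p of 0.042 with an estimated correlation. Fatty acid synthesis genes (18 of 22 higher, 19 adjusted over the list alone, median 1.99, adjusted p = 2.7e-07, 0.303 with an estimated correlation), mitochondrially encoded genes (8 of 8, median 1.17, adjusted p = 5.38e-07, 0.065 estimated) and lipolysis genes (12 of 16, median 0.95, adjusted p = 2.12e-05, 0.065 estimated) also rose. Skeletal muscle genes (31 of 35 lower, median -3.29, adjusted p = 1.15e-09, 0.356 estimated), fibroblast and matrix genes (24 of 37, median -0.96, adjusted p = 1.8e-05, 0.378 estimated) and interferon response genes (15 of 25, median -0.55, adjusted p = 0.00321, 0.355 estimated) fell. Genes of the tricarboxylic acid cycle, PPAR targets, cholesterol synthesis and adipocyte differentiation were higher with medians of 0.37, 0.68, 0.46 and 0.42 (adjusted p = 0.000614, 0.00731, 0.0109 and 0.0406; 0.381, 0.431, 0.519 and 0.355 with an estimated correlation), but these directions turned when libraries were scaled by size alone. Their medians from mean log2 CPM were then -0.25, -0.08, -0.18 and -0.27, against 0.36, 0.49, 0.38 and 0.33 with TMM factors.

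Adult libraries differed from weaned libraries by age and by the high fat diet, which cannot be separated here. Scd1, the main desaturase of fatty acid synthesis, rose from 5146 to 47810 CPM (averages of both diets; log2 fold change 3.29 ± 0.255, edgeR adjusted p = 1.5e-07), and Hephl1 and Gldn by 4.83 ± 0.522 and 4.10 ± 0.307 (adjusted p = 4.48e-06 and 1.04e-07). Of the white adipocyte list, which did not pass as a list, Inhbb and Ccdc3 rose by 3.54 and 3.11 (adjusted p = 1.01e-05 and 3.75e-10). Cyp2b10 fell by 6.56 ± 0.328 and the amino acid transporter gene Slc7a8 by 6.01 ± 0.868 (adjusted p = 1.52e-09 and 7.57e-05). Igfbp3, also of the white adipocyte list, fell by 3.68, and Cfd, which encodes adipsin, by 3.19 (adjusted p = 2.93e-08 and 2.57e-07). The red cell genes Slc4a1 and Hba-a2 fell by 3.02 and 2.95 (adjusted p = 3.65e-05 and 1.22e-07). The macrophage genes Fcgr1 and Mpeg1 rose by 2.95 and 2.05 (adjusted p = 0.00217 and 1.01e-06) and the muscle genes Xirp2 and Cacna1s by 3.88 and 3.69 (adjusted p = 0.000464 and 0.000872). Most of that muscle rise lay in the fish oil libraries. Xirp2 was at 6.395 ± 5.9 CPM in adult and 1.677 ± 2.43 CPM in weaned control libraries, against 293.3 ± 190 CPM in adult and 5.202 ± 2.78 CPM in weaned fish oil libraries (n = 3 each). The muscle list mean was 0.314 ± 1.2 log2 CPM in adult and -0.0426 ± 1.13 in weaned control libraries, against 4.75 ± 1.33 in adult and 1.36 ± 0.122 in weaned fish oil libraries (n = 3 each). Of the genes tested 4461 passed, 2315 higher and 2146 lower (6028 with an unadjusted p under 0.05). Scaling by library size alone shifted the median of all genes by 0.16 and gave 3734 higher and 1176 lower.

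From weaned to adult libraries 8 lists were higher and 3 lower, and none of these 11 passed with an estimated correlation (p between 0.282 and 0.615). Among the higher lists were skeletal muscle (24 of 35 higher, median 2.53, camera adjusted p = 5.01e-08, with most of the rise in fish oil libraries), macrophage (18 of 22, 19 adjusted over the list alone, median 1.02, adjusted p = 1.26e-07) and fatty acid oxidation genes (16 of 24, median 0.42, adjusted p = 3.41e-07). The others were interferon response (11 of 25, median 0.52, adjusted p = 0.000381), tricarboxylic acid cycle (11 of 18, median 0.27, adjusted p = 0.000555) and mitochondrially encoded genes (7 of 8, median 0.41, adjusted p = 0.000794). Proliferation (10 of 32, median 0.68, adjusted p = 0.0074) and cholesterol synthesis genes (6 of 24, median 0.15, adjusted p = 0.0399) were also higher. The cholesterol synthesis list mean was 2.21 to 2.55 log2 CPM in weaned and 3.10 to 3.31 in adult control libraries, but 2.35 to 3.48 and 2.62 to 3.13 in the fish oil libraries. The tricarboxylic acid cycle list mean was 8.37 to 8.57 and 8.86 to 8.91 in control and 8.48 to 8.89 and 8.77 to 8.90 in fish oil libraries. Erythroid (9 of 12 lower, median -2.52, adjusted p = 5.01e-08), endothelial (13 of 22, median -0.49, adjusted p = 6.49e-05) and histone modifying enzyme genes (10 of 39, median -0.16, adjusted p = 0.0404) were lower. The histone list had a median of 0.0076 when libraries were scaled by size alone. The lists of creatine and calcium cycling, inflammatory mediator, nerve and Schwann cell, endoplasmic reticulum stress and immediate early genes passed in none of the 5 comparisons, with lowest adjusted p-values of 0.0912, 0.168, 0.0671, 0.0656 and 0.0855. The lymphocyte, epidermis and cartilage lists had 3 tested members each and were only counted. From fetal to weaned libraries Satb1 of the lymphocyte list fell by 0.69, Sbsn of the epidermis list by 1.93 and Col11a1 of the cartilage list by 2.60 (adjusted p = 0.00443, 8.43e-05 and 3.43e-06).

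**Figure D4:**
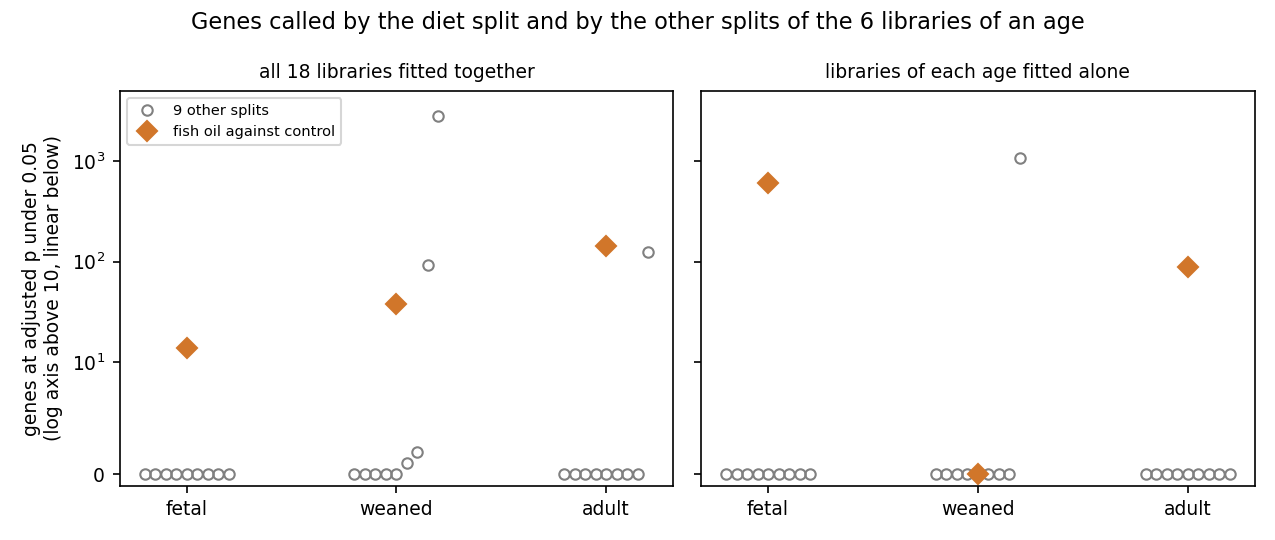
Number of genes called (symmetric log axis) at each age for the real split by diet and for the 9 other splits of the same 6 libraries into 3 and 3, in the shared fit and with each age fitted alone. In the shared fit the diet split called 14, 38 and 142 genes in fetal, weaned and adult libraries and the highest other split 0, 2808 and 126.

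Diet effects at different ages were compared across the 14366 genes, which are not independent replicates, in a family of 3. Pearson's r was 0.118 between fetal and weaned effects (permutation p = 0.04 from 100 relabellings, adjusted p = 0.105), 0.192 between fetal and adult (p = 0.07, adjusted p = 0.105) and 0.161 between weaned and adult effects (p = 0.26, adjusted p = 0.26). Spearman's rho was 0.0501, 0.021 and -0.0114 (p = 0.41, 0.32 and 0.85), so that none passed after adjustment. Without weaned fish oil replicate 2 the fetal and weaned r was 0.0533, and without adult fish oil replicate 2 the weaned and adult r was 0.036.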

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

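The tests with the muscle covariate in adult libraries, with Xist as a covariate, of exchanged labels and of the clock genes, and the edgeR values for the stage of the fetuses, were chosen only after the result they address had been seen. The counts for other splits of the libraries were fixed before the splits were run, but which splits gave them was looked at afterwards.

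The diet effect differed between ages by the test of the difference itself for 18 genes between weaned and fetal, 24 between adult and fetal and 36 between adult and weaned libraries. Of 100 splits, 12, 10 and 15 gave counts as large, with 1550, 134 and 1492 genes as the highest of the others, so chance was not excluded for these counts. The other splits as large did not stand for the absence of an effect, since most carried a structure of the weaned libraries or the adult diet difference. Between weaned and fetal libraries all 11 set weaned control replicates 1 and 2 with fish oil replicate 1, and between adult and fetal libraries all 9 kept the adult diet groups. Between adult and weaned libraries 9 of 14 held that weaned split and 4 kept the adult diet groups, with 2 counted in both. The other 3 held neither and called 55 to 155 genes. Between weaned and fetal libraries the log2 difference was 1.94 for Snx10, 1.24 for Setd7, 2.09 for Aspg, 2.22 for Nabp1, 2.63 for Fasn, 1.425 for Per2 and 0.92 for Cnnm2. It was -0.97 for Shprh and -1.25 for Prkag2. Between adult and fetal libraries it was 1.245 for Setd7, 2.47 for Hr, 1.45 for Snx10, 0.96 for Cnnm2 and -1.49 for Trmt9b. For muscle genes it was 4.68 for Mylk4, 7.10 for Lmod2, 5.46 for Ckmt2, 6.26 for Mylk2 and 5.04 for Ryr1. Adult control libraries held 2 counts of Lmod2 and 3 of Mylk2, so the sizes of those 2 differences depend on the prior count. Between adult and weaned libraries it was -2.85 for Fasn, -1.85 for Insig1, -1.49 for Plin2 and -3.58 for Adprhl1. It was 3.92 for Shox2, 1.83 for Dmd, 4.39 for Tpm2, 4.31 for Pdlim3 and 6.675 for Mb.

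No comparison used the reverse column, which counts reads on the strand opposite to the genes. Its total came to 2.25 to 3.53% of that of the unstranded column in a library, as a ratio of separate counts and not as a share.

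In adult fish oil libraries 29 of 35 muscle genes were higher. The adult depths were close, at 9.23 to 9.66 M counts in control and 7.89 to 9.42 M in fish oil libraries, which argued against depth. With all libraries thinned to 7.88 M counts 100% of the 29 calls were made again. That test could hardly come out otherwise, since it took few counts from the adult libraries. Muscle tissue in the samples is a candidate source: 89.7% of the 29 genes had a ratio of fish oil replicate 1 to 3 within 1 log2 unit of their median of 2.45. Ttn and Myh4, the most abundant list genes in fish oil libraries, were chosen after their values were seen. They were at 4940 ± 3560 and 885 ± 548 CPM against 94.8 ± 80.4 and 19 ± 20.9 in control. Of the 35 genes, 6 had a mean of at least 5 CPM in control libraries and 0 were in another list. Outside the list 110 genes were called higher, and 95 of them had a correlation above 0.9 with the muscle list mean. A diet difference shared with that mean also raises such a correlation. An effect within brown fat cells stays open, because muscle share and diet go together here: with the muscle mean as a covariate edgeR called 0 genes (774 with an unadjusted p under 0.05; DESeq2 2, limma-voom 0).

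In fetal libraries fitted alone, 177 of the genes lower with fish oil rose with age and 58 fell, while 121 of those higher with fish oil fell with age and 63 rose. With log2 CPM of Xist as a covariate 526 genes were called. Xist overlapped between the diets, at 1.957 to 329.3 CPM in control and 6.252 to 158.9 CPM in fish oil libraries. That covariate could therefore take up little of a diet difference, and a mix of male and female tissue stays open. Muscle share stays open, although 86.4% of the median size of the effect was left with the muscle covariate. The muscle list mean lay apart by diet, at 3.71 to 4.43 log2 CPM in fish oil and 2.65 to 3.44 in control libraries. The muscle covariate therefore cannot be separated from diet in the fetal libraries. That covariate took the median from 0.533 to 0.46, the standard error from 0.104 to 0.18 and the calls from 604 to 17, so the calls ended with both a smaller effect and a larger error. An earlier stage of the fish oil fetuses may contribute: genes falling most with age exceeded those rising most by 0.345 in their diet difference of mean log2 CPM (medians 0.146 and -0.199), past the bound set beforehand, while another split gave 0.341. From edgeR log2 fold changes the difference was 0.552 (medians 0.145 and -0.406) and the highest other split 0.412. The median of the rising genes changed with the basis used and that of the falling genes hardly did. The size of the difference thus depends on that basis, through the genes that rise with age. Yet 10 splits are too few for a share under 0.05. It was left open only after the first value was seen, also because proliferation and fibroblast genes, which fell with age by medians of -2.64 and -0.96, had diet medians of 0.03 and -0.06.

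In weaned libraries the clock list was higher with fish oil, also with an estimated correlation (adjusted p = 0.0265). The fatty acid synthesis list was higher with the preset correlation but not with an estimated one (adjusted p = 0.2), and fish oil replicate 1, at 6.20 log2 CPM, lay within the control range of 6.04 to 6.75. The clock list mean ran at 3.66 to 3.71 in control and 4.06 to 4.16 in fish oil libraries, with a largest range of 0.0974 within a group. The clock list mean thus did not follow the split of control replicates 1 and 2 with fish oil replicate 1 from the rest. It overlapped between the sides of that split (gap -0.452), while the mean of fatty acid synthesis genes did not (gap 0.5). The overlap for clock genes was fixed once their diet groups were seen to lie apart. It is therefore no separate test, and other structure of the libraries stays open for clock genes. An effect of the maternal diet on clock genes stays open and was not tested. For fatty acid synthesis genes a structure of the libraries other than the diet labels is a candidate explanation: that split called 2808 genes, and 1076 in weaned libraries alone. The split still kept control replicates 1 and 2 apart from fish oil replicates 2 and 3, so it partly followed diet. Its count therefore cannot show that such a structure is unrelated to diet. Exchanged labels of 1 control and 1 fish oil library stay open for all genes, with groups that did not overlap for 10.2% of genes where chance gives 10%. The share of mt-Rnr2 ran with the labels, at 58.36 to 61% in control and 53.12 to 54.92% in fish oil libraries, as did the clock list. The means of the fatty acid oxidation list, higher with fish oil, and of the histone modifying enzyme list, lower with fish oil, also ran with the labels. The gene and these lists do not decide this: the means of 3 of 26 lists did not overlap, where chance gives 2.6. An effect of the diet on lipid synthesis also stays open, since the fatty acid synthesis median of 1.26 was below the 1.48 of another split and 10 splits are too few for a share under 0.05.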

How the results depend on the processing

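Unstranded counts, library size alone, removal of mitochondrial rRNA genes, covariates and the added variants of ages fitted alone were tests chosen after the data were seen. For each change given here, the cause was not tested. Age gene counts were within 1.5 times in 11 settings each and moved in 2. A limit of 1.5-fold gave 4829 genes from fetal to weaned and 2591 from weaned to adult libraries, and the muscle covariate 3559 and 1991. DESeq2 gave 71 fetal, 218 weaned, 137 weaned to fetal, 77 adult to fetal and 169 adult to weaned genes, and limma-voom gave 412, 1209, 746, 44 and 534. With no filter there were 240 fetal, 770 weaned and 546 adult genes and 352, 313 and 555 for the 3 differences. A filter of 50 counts gave 84 adult genes and 36 for the weaned to fetal difference. Fitting only the ages compared gave 604 fetal, 0 weaned (edgeR; 643 with an unadjusted p under 0.05, DESeq2 18) and 89 adult genes, and 5, 186 and 1 for the differences. The muscle covariate gave 8 fetal and 3 weaned genes, 5 for the adult to weaned difference, 0 adult genes (774 with an unadjusted p under 0.05, DESeq2 2) and 0 for the adult to fetal difference (818, DESeq2 9), and 3 fetal lists. Library size alone gave 63 weaned genes, 28 for the weaned to fetal and 63 for the adult to weaned difference. The replicate block gave 21 weaned genes, 9 for the adult to fetal and 19 for the adult to weaned difference, and r = 0.118 (p = 0.06) between fetal and weaned effects. Of the genes for the adult to weaned difference 58.3% were higher, but 49.7% with DESeq2, 42.9% with library size alone, 37.8% with limma-voom, 20% with the muscle covariate and 0 to 82.5% with 1 library left out. Of the fetal genes 21.4% were higher, but 55.4% with no filter. An estimated correlation left 0 fetal, 1 weaned and 1 adult list, 4 from fetal to weaned and 0 from weaned to adult libraries, and fry called 0 fetal, 1 adult and 17 weaned to adult lists.

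The fetal and weaned correlation was 0.0501 by Spearman's rho (p = 0.41), 0.0874 in genes of higher mean expression (p = 0.41) and 0.0976 without tissue list genes (p = 0.11), and the weaned and adult correlation turned to -0.0114 by Spearman's rho (p = 0.85). Leaving out 1 library gave 2 to 10 fetal, 2 to 1632 weaned and 89 to 197 adult genes, and 4 to 467, 2 to 104 and 1 to 813 for the differences from weaned to fetal, adult to fetal and adult to weaned libraries. It gave 6838 to 7893 and 3795 to 4689 genes for the ages. It gave 298 to 582 genes in fetal, 0 to 50 in weaned and 0 to 190 in adult libraries fitted alone. Lists numbered 4 to 6 in fetal, 10 to 13 in weaned and 2 to 6 in adult libraries, and 13 to 15 and 9 to 14 for the ages. Correlations ran from 0.0533 to 0.156 for fetal and weaned, 0.13 to 0.223 for fetal and adult and 0.036 to 0.219 for weaned and adult effects. At 3.87 to 7.46 M counts outside mitochondrial rRNA, depth limits genes near the floor of 0.145 to 0.433 CPM. In libraries fitted alone, DESeq2 gave 18 weaned and 214 adult genes, limma-voom 0 adult genes (1018 with an unadjusted p under 0.05), the muscle covariate 17 fetal and 0 adult genes (373, DESeq2 3) and the replicate block 4 adult genes.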

Other observations

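The single genes of iron, haem and redox handling, the glucocorticoid targets and their test were chosen after their values were seen; the counts for other splits were not.

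In fetal libraries fitted alone, Tfrc, the transferrin receptor, rose from 249.6 ± 26.6 CPM in control to 568.7 ± 149 CPM in fish oil libraries (log2 fold change 1.19 ± 0.141, edgeR adjusted p = 0.000352). Alas1, the first enzyme of haem synthesis, rose by 0.81 ± 0.12 (adjusted p = 0.00154) and Aco1, an iron sensor, by 0.39 (adjusted p = 0.0286). Slc40a1, the iron exporter, fell by 1.27 ± 0.164 (adjusted p = 0.000573). The glutathione genes Gclm and Gclc fell by 0.63 and 0.58 (adjusted p = 0.0055 and 0.0247) and Txnrd1 by 0.37 (adjusted p = 0.0148). Fth1, Ftl1, Bach1 and Blvrb gave -0.06, -0.24, 0.18 and -0.07 and did not pass (adjusted p = 0.65, 0.685, 0.294 and 0.849). In the shared fit none of these genes passed. They form no fixed list and were not tested as a set.

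A lower glucocorticoid signal in fetal fish oil libraries is a hypothesis found from these data. Of 14 textbook targets, 50% (7) were lower in all 3 fish oil than in all 3 control libraries, against 10.9% of all genes and 5% by chance. In fetal libraries alone 5 were called lower and 0 higher, among them Klf9 at -0.74 (adjusted p = 0.000592) and Tsc22d3 at -0.69 (adjusted p = 0.0014). The bound of the test was set after the values were seen and the result lies on it, so it decides nothing and the hypothesis stays open.

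Xist, which is expressed from an inactive X chromosome, was at 189.7, 329.3 and 1.957 CPM in fetal control and 158.9, 6.252 and 138.9 CPM in fetal fish oil replicates 1 to 3. The Y-linked gene Ddx3y was at 34.38 to 98.09 CPM in these 6 libraries. In weaned and adult libraries Xist was at most 2.127 CPM.

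At each age 10 splits are too few for a share under 0.05. The diet split called 14 genes in fetal libraries in 1 of 10 splits as large (highest other 0), 38 in weaned libraries in 3 of 10 (2808) and 142 in adult libraries in 1 of 10 (126). Fitted alone these were 604 (1 of 10, highest other 0), 0 (10 of 10, 1076) and 89 (1 of 10, 0). Lists numbered 5 in fetal (1 of 10, highest other 4), 11 in weaned (3 of 10, 12) and 5 in adult libraries (5 of 10, 8). For the ages chance was excluded for the gene counts, 7478 (1 of 100, highest other 3398) and 4461 (1 of 100, 1646). It was not excluded for the lists, 14 (11 of 100, highest other 17) and 11 (16 of 100, 14), although 7 of the 10 and 8 of the 15 other splits as large kept the ages apart within at least 1 diet.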
